A study of Mus musculus with 10 samples.

How the data were processed

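The series holds 10 RNA sequencing libraries from full-thickness dorsal mouse skin, read on an Illumina Genome Analyzer IIx. Reads were processed with cutadapt 1.6, TopHat2 2.0.12, HTSeq (version not given) and Cufflinks 2.2.1 against the mm10 genome, per the submitters' processing notes, which give neither their order nor their settings. Per the file headers, each deposited table gives a count and an FPKM value for each of 24358 gene symbols. The deposited count values are whole numbers that sum to a different total in each library, so they were taken as raw read counts. The deposited FPKM values are normalised to transcript length and library size by the authors, and they were used here only for 1 alternative test and for a check of genes without counts. The annotation, the strand setting and the handling of reads that map to several genes are not given in the sources used here, so members of multigene families (such as Sprr2, Lce, Saa and Krtap genes) and overlapping genes are uncertain. Between 102 and 120 genes per library had a count of 0 and an FPKM above 1. Ribosomal Rn45s took 1.14 to 2.25% of the counts and the transgene Il17c 0.0529 to 1.39%.

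Groups were taken from the genotype and skin type in the labels, and the mouse number from the same labels. All 10 libraries were used and none was left out. The highest correlation of log CPM between 2 libraries was 0.986, and no 2 libraries held identical values. The lowest was 0.837. Which mice were taken at which of the ages stated for the series is not given in the sources used here, so age was not separated from genotype in any genotype comparison. This includes the hair follicle genes in uninvolved skin, since the hair cycle stage changes with age.

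Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by edgeR's filter on low counts (filterByExpr with the groups), libraries were scaled by TMM, and each comparison was tested with robust quasi-likelihood fits and F tests. P-values were adjusted by the Benjamini-Hochberg method with a false discovery rate (FDR) threshold of 0.05. Lesional and uninvolved skin were compared in 1 fit of all 10 libraries with the mouse as a block and 1 lesional effect per genotype, because the design text states that both biopsies came from each mouse. The difference of the 2 lesional effects was tested in the same fit. Genotypes were compared within lesional and within uninvolved skin, each with 5 libraries from 5 different mice, so that no mouse counted as more than 1 replicate. Standard errors of log2 changes were taken from the change and its F statistic. In the fit of all 10 libraries the spread is shared over the 5 mice, and the number of mice beside a standard error is that of the comparison. For genes with few counts in a group, such as Cxcl5, these standard errors depend on the prior count and can understate counting error. Per-library values are CPM scaled by TMM, and differences per mouse are of log2 CPM with a prior count of 2. Across 16083 genes the median log2 change was -0.02 in IL-17C+ mice and 0.00 in the libraries labelled IL-17C+KO. Intervals of ratios of counts are exact (Clopper-Pearson) and, like the limit of 3 counts, cover counting error only.

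Before the data were examined, 29 gene lists were fixed for skin inflammation, keratinocyte states, immune cells, stroma, muscle, fat, pigment, nerve, blood, hair and stress, and 28 of them had enough tested members for a list test. They were tested with camera (limma 3.58.1) with a preset correlation of 0.01 and again with an estimated correlation, with fry beside it, and adjusted over the lists of a comparison. For single members, the FDR was taken over all genes and also adjusted over the list alone. The genes to be named were fixed in the same way. Il6 and Il17c came first. After them came genes past the threshold with a mean of at least 2 CPM, an established symbol and the same direction in every mouse (for genotype comparisons, groups that do not overlap), the 10 largest changes in each direction for paired comparisons and 6 for the others; where fewer than 6 passed, all were named. For each list, up to 4 members with the smallest p were named. Coordinates are from GENCODE M21 (GRCm38, the same assembly as mm10), in which 23281 of the 24358 symbols name a single gene.

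Pairing comes from the labels and the design text, which tie 2 biopsies to each mouse. The deviations of the 2 libraries of a mouse from their group means had correlations of 0.034, -0.07 and -0.122 in IL-17C+ mice and -0.072 in both IL-17C+KO mice, where with 2 mice the value is the same by construction. Between different IL-17C+ mice the correlations were -0.081 to 0.131. By this measure the 2 biopsies of a mouse were no more alike than those of different mice.

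The tests were tried on simulated data with 200 changed genes. These were drawn only from genes above a minimum mean CPM, so the rates do not cover tested genes with lower counts. Each gene was drawn independently around a mean shared by all libraries, with no differences between mice or in tissue composition. The rates that follow hold for that setting and need not hold for these data. In the comparison of IL-17C+ mice, edgeR found 70% of 4-fold and 94% of 8-fold changes, and 15 of its 149 calls were false. For the libraries labelled IL-17C+KO it found 40% and 84%, for the interaction 4% and 46%, for lesional skin 50% and 92%, and for uninvolved skin 28.6% and 80%. DESeq2 1.42.0 found more, with 74 false calls among 226 in IL-17C+ mice and 84 among 217 in IL-17C+KO mice.

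Alternatives chosen before the counts were seen were DESeq2, relative log expression size factors, no filter on low counts, a filter at a mean of 5 CPM, leaving out each mouse, no mouse block, the libraries of 1 genotype only, all 10 libraries for the genotype comparisons, and for the lists an estimated correlation. Pseudocount alternatives applied only to files without counts and were not used. Added after the data were seen were limma-voom, limma on log2(FPKM + 0.1), the mean log2 CPM of the anagen hair follicle list as a covariate, and a comparison of lesional with uninvolved skin averaged over the 5 mice. Summaries and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.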

Results

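RNA from 10 full-thickness biopsies of dorsal mouse skin was sequenced. The biopsies came from 5 mice on a C57Bl/6 background that carry an interleukin-17C (IL-17C) transgene and develop psoriasis-like lesions. Each mouse gave 1 biopsy of lesional skin and 1 of uninvolved skin. The labels call 3 of the mice IL-17C+ (mice 2237, 2275 and 2296) and 2 of them IL-17C+KO (mice 2392 and 2465), where the knocked-out gene is interleukin-6 (Il6) according to the title of the series. The values used were counts of reads per gene for 24358 gene symbols. In each library 17790 to 18431 genes had at least 1 count. In uninvolved skin the libraries held 24855680 counts (mouse 2275), 21056850 (2296) and 26386691 (2237) for IL-17C+, and 26344903 (2465) and 23841342 (2392) for IL-17C+KO. In lesional skin they held 23927869 counts (2275), 26288208 (2296) and 31072491 (2237) for IL-17C+, and 21483189 (2465) and 25627124 (2392) for IL-17C+KO. At these depths 3 counts, the limit that a count of 0 allows, correspond to between 0.0965 and 0.142 CPM (counts scaled to the library total).

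The targeted gene went against the genotype label. Il6 (GRCm38 chromosome 5, 30013114 to 30019981) had 4, 6 and 9 counts in the uninvolved libraries labelled IL-17C+ and 55 and 71 in those labelled IL-17C+KO. In lesional libraries it had 18, 26 and 69 counts under the label IL-17C+ and 300 and 315 under the label IL-17C+KO. The mean was 0.276 ± 0.107 CPM (SD, n = 3) against 2.64 ± 0.752 CPM (SD, n = 2) in uninvolved skin, and 1.40 ± 1.14 CPM (SD, n = 3) against 12.6 ± 1.06 CPM (SD, n = 2) in lesional skin. The values are sums over the whole gene and cannot show which exons were covered, so a disrupted allele that is still transcribed would be counted. The libraries are therefore named below by their labels, and every direction between genotypes rests on those labels. Il17c (GRCm38 chromosome 8, 122422020 to 122423639), the transgene, was abundant in all 10 libraries. It ranged from 534.6 CPM (uninvolved, mouse 2465) to 15180 CPM (uninvolved, mouse 2237). The lesional minus uninvolved difference of Il17c was 2.94, 1.21 and -0.52 log2 units in mice 2275, 2296 and 2237, and 4.35 and 0.30 in mice 2465 and 2392.

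**Figure D1:**
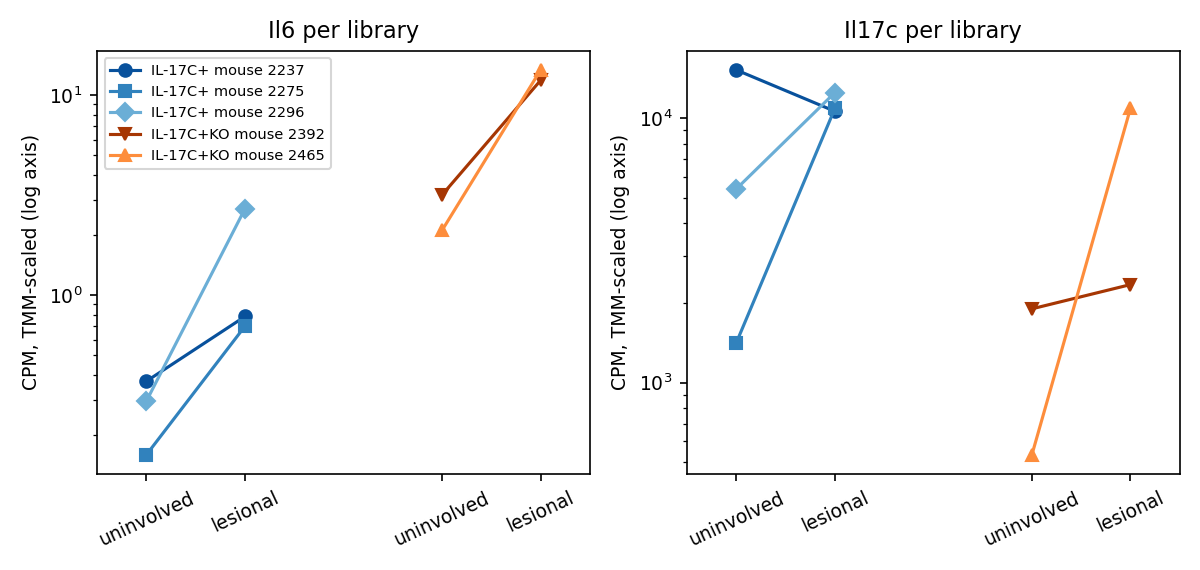
CPM of Il6 (left) and Il17c (right) in each of the 10 libraries on a log axis, with a line joining the uninvolved and lesional biopsy of each mouse; blue marks are mice labelled IL-17C+ and orange marks those labelled IL-17C+KO. All 4 IL-17C+KO libraries lie above the IL-17C+ libraries of the same skin type for Il6 (lowest 2.11 against highest 0.371 CPM in uninvolved skin), and Il17c is lower in the lesional than in the uninvolved biopsy of mouse 2237 alone.

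The first comparison asked how lesional skin differs from uninvolved skin of the same IL-17C+ mice. The smallest p-values among the fixed gene lists belonged to 2 chemokines that attract neutrophils and to a cytokine. Cxcl5 was 6.32 ± 0.55 log2 units higher in lesional skin (SE, 3 mice), with 1, 2 and 3 counts in the uninvolved and 77 to 621 in the lesional libraries. Pooled over the 3 mice this is a ratio of 115.5 per total count, with a 95% counting interval of 52.8 to 316. Cxcl3 was 5.08 ± 0.58 log2 units higher and oncostatin M (Osm), a cytokine of the IL-6 family, 4.49 ± 0.54 higher, in 3 of 3 mice each. None of these passed the threshold over all genes. With edgeR's quasi-likelihood test and the mouse as a block, 0 of 16083 genes had a Benjamini-Hochberg adjusted p under 0.05, and the smallest was 0.12 (Cxcl5). At an unadjusted p under 0.05 there were 1031 genes (569 higher, 462 lower) where chance gives 804. Other splits of these libraries that part every pair gave 1347, 1396 and 70 genes in the same fit. The excess alone therefore does not show a lesional effect. limma-voom also called 0 genes, whereas DESeq2 called 247 (155 higher, 92 lower).

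Tissue remodelling genes moved together in these mice. Of 22 genes for proteases and matrix remodelling, 16 rose at a false discovery rate (FDR) of 0.05 adjusted over the list alone and 0 over all genes tested. Among them were Timp1, an inhibitor of metalloproteinases (log2 change 2.17 ± 0.41), and the gelatinase Mmp9 (2.07 ± 0.41). The camera test placed the list above other genes (adjusted p = 8.79e-19 with a preset correlation of 0.01, adjusted p = 0.318 with an estimated correlation). Of 20 genes for fibroblasts and collagen, 12 rose adjusted over the list alone, including Loxl1 (1.37 ± 0.26), elastin (Eln, 1.51 ± 0.34) and Col5a1 (2.11 ± 0.50), with camera adjusted p = 1.11e-15 (adjusted p = 0.318 with an estimated correlation). Of 13 tested neutrophil genes, 9 rose adjusted over the list alone, including Clec4d (3.55 ± 0.75), Trem1 (4.26 ± 1.08) and the formyl peptide receptors Fpr2 (2.24 ± 0.51) and Fpr1 (4.31 ± 1.13), with camera adjusted p = 3.1e-15 (adjusted p = 0.318 with an estimated correlation). In mouse 2237 the differences of these genes were 1.41, 0.70, 1.58 and 0.64, in that order. They ran from 1.22 to 6.25 in mice 2275 and 2296. Of 13 mast cell and eosinophil genes, 5 passed adjusted over the list alone, led by the receptor Kit (0.91 ± 0.25) and the mast cell proteases Cpa3 (0.97 ± 0.28) and Tpsb2 (1.37 ± 0.40). That list had camera adjusted p = 1.04e-06 (adjusted p = 0.318 with an estimated correlation).

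Signalling genes passed in smaller numbers. Adjusted over the list alone, 3 of 33 chemokines rose (Cxcl5, Cxcl3 and the monocyte attractant Ccl2, 1.22 ± 0.26), as did 2 of 17 IL-1 family genes (Il33, 1.34 ± 0.29, and the receptor subunit Il18rap, 1.84 ± 0.45) and 1 of 17 IL-6 family genes (Osm). Of 23 other cytokines, Il19 (3.46 ± 0.65) and the neutrophil growth factor Csf3 (3.45 ± 0.76) rose and the epithelial cytokine Tslp fell by 1.47 ± 0.35. For the 4 lists the camera adjusted p was 4.73e-05, 0.014, 0.00261 and 0.00334, and with an estimated correlation the adjusted p was 0.367, 0.395, 0.318 and 0.367. Il6 itself had a log2 difference of 2.11 ± 0.53 (adjusted p = 0.62, and 0.0507 adjusted over the list alone). The matrix protein tenascin C (Tnc, 3.55 ± 0.69) alone passed among 24 genes of keratinocyte activation, and the stress keratins Krt6b and Krt6a had log2 differences of 3.25 ± 0.84 and 2.50 ± 0.68. Medians over this list were 3.33, 1.14 and -0.01 in mice 2275, 2296 and 2237. The antimicrobial list had no member past the threshold, with medians of 2.85, 2.36 and 0.02 in the same mice. Both lists were called by camera (adjusted p = 2.07e-10 and 2.53e-09) but not with an estimated correlation (adjusted p = 0.40 and 0.367).

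Camera called 18 of 28 lists in this comparison, 15 upwards and 3 downwards, and with an estimated correlation 0, as did the self-contained fry test (0 lists). Besides those named, the cell cycle (median log2 change 0.57), monocyte and macrophage (0.46), endothelium (0.42), immediate early (0.58) and anagen hair follicle (1.09) lists were called upwards, with adjusted p = 0.656, 0.675, 0.367, 0.656 and 0.68 with an estimated correlation. With single mice left out, the median ranged from 0.16 to 1.03 for cell cycle and from 0.088 to 0.77 for monocytes and macrophages. It ranged from 0.11 to 0.64 for endothelium and from 0.080 to 0.69 for immediate early genes. Skeletal muscle (median -1.80, 22 of 24 members negative), adipocytes (-0.78) and sebaceous gland (-0.37) were called downwards, with adjusted p = 0.467, 0.656 and 0.68 with an estimated correlation. The hair follicle value came from 1 mouse. Its median was 8.59 in mouse 2275 and -0.60 and -0.27 in mice 2296 and 2237, and without mouse 2275 the fitted median was -0.47. Not called were the IL-17 axis, cornified envelope, basal and spinous keratinocytes, interferon response, T cells, B and plasma cells, dendritic cells, melanocytes, Schwann cells and red blood cells.

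**Figure D2:**
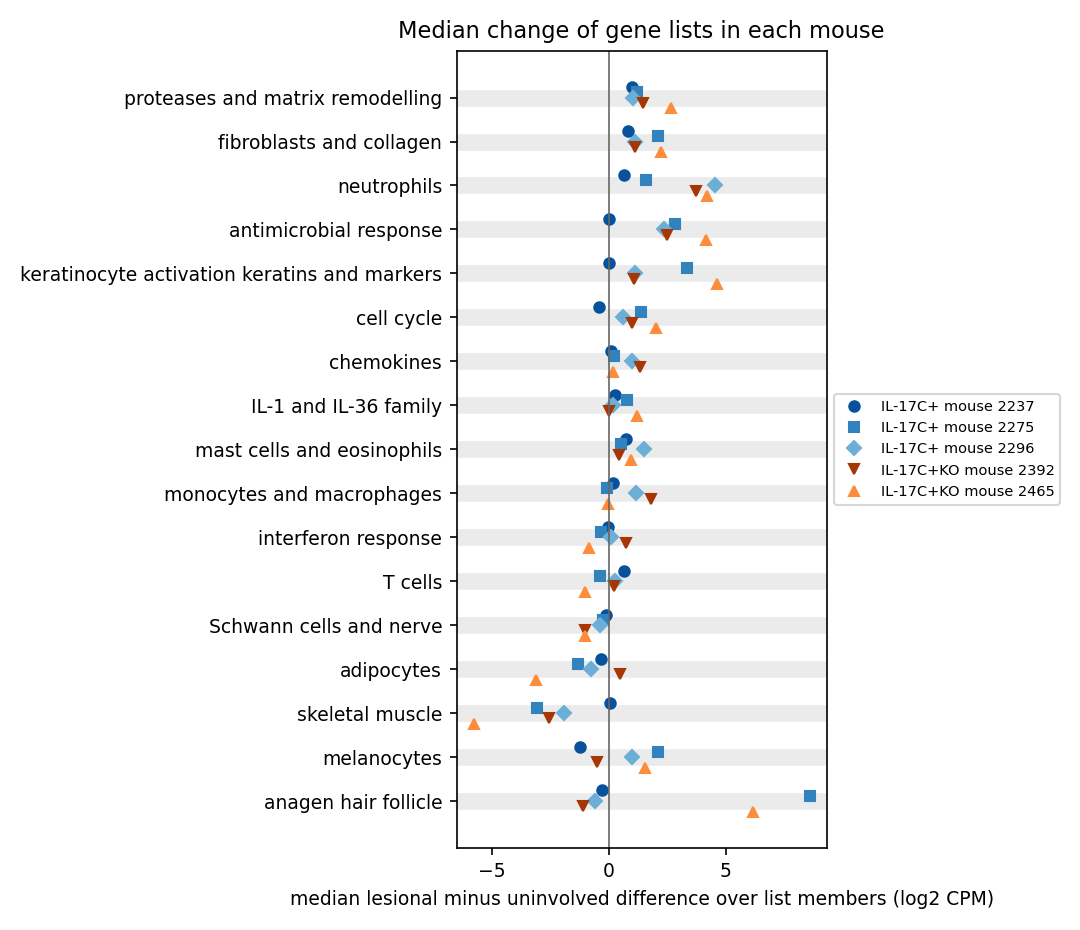
Median lesional minus uninvolved difference (log2 CPM) over the members of 17 gene lists, 1 mark per mouse; blue marks are mice labelled IL-17C+ and orange marks those labelled IL-17C+KO. Proteases and matrix remodelling lies above 0 in all 5 mice (0.99 to 2.66), and anagen hair follicle spans from -1.09 to 8.59.

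The same question was asked of the libraries labelled IL-17C+KO. Here 2 genes passed the threshold. Cxcl5 (GRCm38 chromosome 5, 90759360 to 90761624) rose by 12.33 ± 0.78 log2 units (SE, 2 mice; adjusted p = 0.0288), from 2 and 0 counts in the uninvolved libraries to 7954 and 2184 in the lesional ones. The fitted size depends on the prior count, and the ratio of the pooled counts was 5400 with a 95% counting interval of 1494 to 44600. The SE rests on a spread shared by all 5 mice and understates this counting error. Csrp3 (GRCm38 chromosome 7, 48830398 to 48848033), which encodes the muscle LIM protein of striated muscle, fell by 6.02 ± 0.45 log2 units (adjusted p = 0.0387), from a mean of 636 ± 533 CPM to 10.6 ± 10.1 CPM (SD, n = 2). Both genes moved the same way in the 3 IL-17C+ mice. At an unadjusted p under 0.05 there were 2166 of 16083 genes (991 higher, 1175 lower) where chance gives 804. Other splits of these libraries were not run, so the excess alone does not show a lesional effect. limma-voom called 2 genes and DESeq2 called 1157 (515 higher, 642 lower). Both calls were lost without the mouse block (adjusted p = 0.114 for Cxcl5 and 0.121 for Csrp3), in the 4 IL-17C+KO libraries alone (0.181 for each), and without mouse 2296, 2392 or 2465. Cxcl5 then had an adjusted p of 0.0532, 0.107 and 0.453, and Csrp3 of 0.213, 0.158 and 0.627.

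Chemokines and cytokines were again prominent. Adjusted over the list alone, 11 of 33 chemokines rose and 1 fell. Besides Cxcl5, the smallest p belonged to Ccl2 (3.55 ± 0.34), Cxcl3 (6.91 ± 0.69) and the monocyte attractant Ccl7 (3.53 ± 0.43). In the IL-6 family 4 of 17 rose, namely Osm (4.81 ± 0.59), Il6 (2.28 ± 0.56), the feedback inhibitor Socs3 (2.09 ± 0.53) and Lif (3.35 ± 0.86). Of 23 other cytokines, 3 rose, namely Il19 (7.22 ± 0.90), Csf3 (6.07 ± 0.83) and Il24 (5.71 ± 1.33). The uninvolved libraries held 1 and 3 counts of Il19, and its ratio of pooled counts was 185.1 (95% counting interval 72.0 to 681). In the IL-1 family 5 of 17 rose, with Il1r1 (1.64 ± 0.29), Il18rap (2.95 ± 0.56), Il33 (1.85 ± 0.36) and Il1b (5.03 ± 1.14) leading. The 4 lists had camera adjusted p = 1.77e-09, 0.000513, 6.56e-05 and 0.000285, and each had adjusted p = 0.20 with an estimated correlation.

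Antimicrobial, keratinocyte and cell cycle genes passed within their own lists in part. Adjusted over the list alone, 5 of 19 antimicrobial genes rose. Among them were lipocalin 2 (Lcn2, 3.30 ± 0.51), Chil3 (4.03 ± 0.65) and the acute phase proteins Saa1 (5.13 ± 0.91) and Saa3 (8.12 ± 1.44). In keratinocyte activation 4 of 24 rose, namely Il4ra (1.64 ± 0.28), Tnc (5.46 ± 0.93), Krt6b (4.80 ± 1.15) and Krt6a (3.66 ± 0.93). All 40 cell cycle genes had positive values and 27 rose adjusted over the list alone, with Tpx2 (1.86 ± 0.44) and Plk1 (1.99 ± 0.51) leading. Camera gave adjusted p = 1.97e-17, 1.18e-12 and 3.55e-20 for the 3 lists, and adjusted p = 0.20, 0.284 and 0.284 with an estimated correlation. In proteases and matrix remodelling 19 of 22 rose and 1 fell, with Timp1 (4.62 ± 0.54), Mmp19 (2.16 ± 0.30), Mmp3 (3.56 ± 0.50) and the prostaglandin synthase Ptgs2 (5.03 ± 0.85) leading. Fibroblast genes passed in 12 of 20 cases (Pdgfra, 1.43 ± 0.26, and Col5a2, 2.42, lead) and neutrophil genes in 11 of 13 (Fpr2, 3.87 ± 0.61, and Clec4d, 4.90 ± 0.91, lead). These 3 lists had adjusted p = 5.19e-23, 2.63e-11 and 1.16e-18 in camera and 0.20 each with an estimated correlation. The endothelial selectins Selp (2.39 ± 0.35) and Sele (2.67 ± 0.44) rose adjusted over the list alone, as did the mast cell genes Hdc (2.35 ± 0.57) and Fcer1a (2.97 ± 0.78); their lists had adjusted p = 0.433 and 0.284 with an estimated correlation.

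Many skeletal muscle genes and some myelin genes fell within their own lists. All 24 skeletal muscle genes had negative values and 17 fell adjusted over the list alone, including myoglobin (Mb, -4.81 ± 0.83) and the fast-fibre light chains Mylpf (-4.55 ± 0.86) and Myl1 (-4.64 ± 0.91). Camera gave adjusted p = 2.86e-25 (adjusted p = 0.218 with an estimated correlation). Of 12 Schwann cell and nerve genes, 4 fell in the same way, led by the myelin genes Prx (-1.75 ± 0.39) and Ncmap (-1.60 ± 0.41), with adjusted p = 0.20 with an estimated correlation. Camera called 20 of 28 lists, 16 upwards and 4 downwards, and 0 with an estimated correlation, and fry called 0. The remaining calls were upwards for monocytes and macrophages (median 0.94), B and plasma cells (1.15), immediate early genes (0.78) and hair follicle (2.56), and downwards for adipocytes (-1.20) and sebaceous gland (-0.48), with adjusted p between 0.284 and 0.808 with an estimated correlation. Without mouse 2465 the medians were -1.23 for hair follicle, 0.49 for adipocytes, 0.088 for sebaceous gland and -0.064 for immediate early genes, and without mouse 2392 that of monocytes and macrophages was -0.054. Not called were the IL-17 axis, cornified envelope, basal and spinous keratinocytes, interferon response, T cells, dendritic cells, melanocytes and red blood cells. For 3 of these the median and the mean differed in sign: cornified envelope (-0.10 and 0.81), interferon response (0.03 and -0.01) and red blood cells (-1.10 and 0.48).

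**Figure D3:**
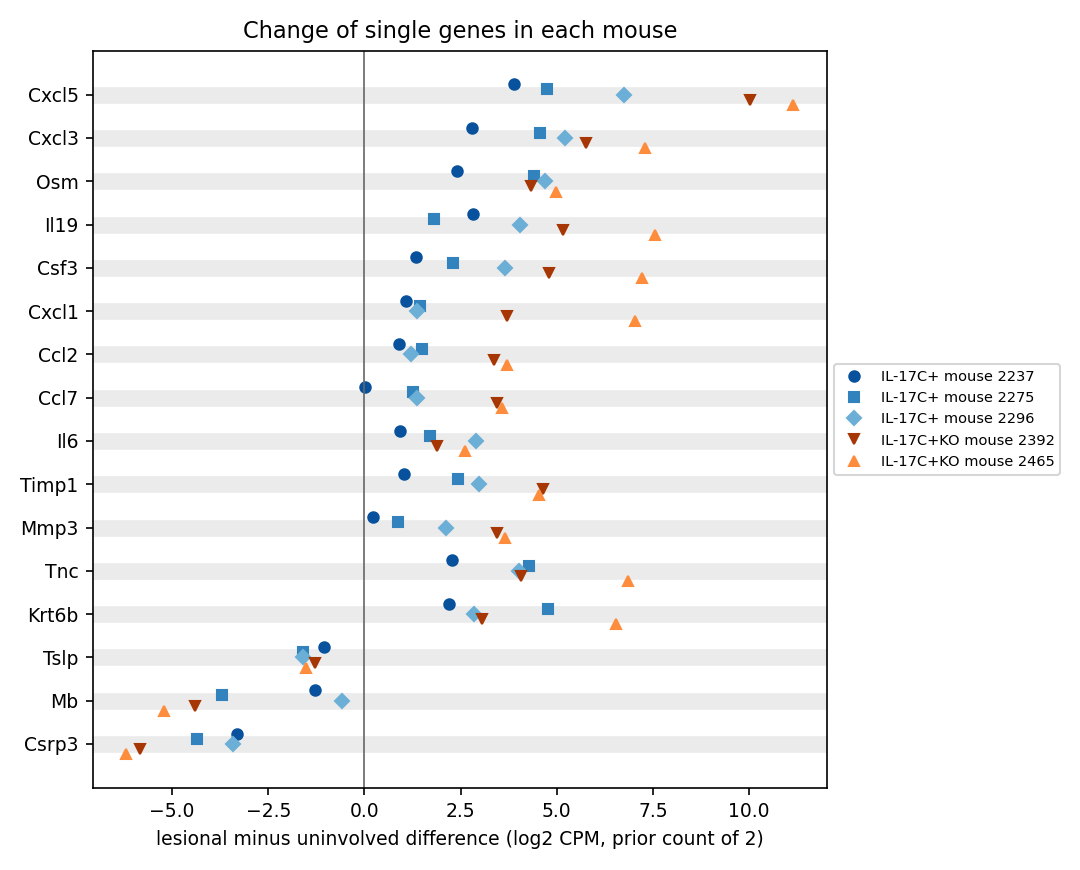
Lesional minus uninvolved difference of log2 CPM (prior count of 2) for 16 genes, 1 mark per mouse; blue marks are mice labelled IL-17C+ and orange marks those labelled IL-17C+KO. Cxcl5 lies at 3.89 to 6.75 in the first group and at 10.02 and 11.15 in the second, and Csrp3 and Mb lie below 0 in all 5 mice.

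Whether the lesional change itself differs between the genotype labels was tested as an interaction. Across 16083 genes, which are not independent replicates, the 2 sets of log2 changes had a Pearson r of 0.789 and a Spearman rho of 0.711, and the 2 sets come from different mice. Of the 200 genes with the smallest p in IL-17C+ mice, 200 had the same sign in IL-17C+KO mice, and of all genes 74.5% did. No gene had a significant interaction in edgeR's quasi-likelihood test (0 of 16083; 188 genes at an unadjusted p under 0.05 where chance gives 804; smallest adjusted p = 1). limma-voom called 0 and DESeq2 called 6. Adjusted over the list alone, the change was larger in the mice labelled IL-17C+KO for 4 of 33 chemokines: Ccl2 by 2.34 ± 0.40, Cxcl5 by 6.01 ± 1.08, Ccl7 by 2.63 ± 0.52 and Cxcl1 by 4.05 ± 1.001 log2 units. The Cxcl5 value rests on pooled uninvolved counts of 6 in IL-17C+ and 2 in IL-17C+KO mice, so its size and its SE depend on the prior count. DESeq2 called the same 4 chemokines, together with negative differences for Csrp3 (-2.32) and Tceal7 (-4.56). Csrp3 thus fell further in the mice labelled IL-17C+KO. Lesional Ccl2 averaged 10.3 ± 4.32 CPM (SD, n = 3) in IL-17C+ mice and 63.5 ± 16.6 CPM (SD, n = 2) in those labelled IL-17C+KO, and Cxcl1 averaged 12.4 ± 9.53 CPM (SD, n = 3) and 188 ± 102 CPM (SD, n = 2). Camera called 12 lists upwards and 2 downwards for the interaction. Skeletal muscle (median difference -2.54), antimicrobial response (2.21), neutrophils (1.63), keratinocyte activation (1.29), proteases and matrix remodelling (1.03) and cell cycle (0.86) were the largest. With an estimated correlation the adjusted p of these 6 was 0.317, 0.317, 0.317, 0.537, 0.317 and 0.41, and 0 lists were called. Without mouse 2465 the median of keratinocyte activation was -0.24.

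The genotype labels were then compared within lesional skin, 2 libraries against 3. Some IL-6 family genes, chemokines and endothelial genes were higher in the libraries labelled IL-17C+KO when adjusted over their own lists, and none over all genes. Adjusted over the list alone, 8 of 17 IL-6 family genes were higher, including Lif (2.11 ± 0.40), the oncostatin M receptor Osmr (0.84 ± 0.16), Jak2 (0.74 ± 0.16) and Il6 (3.21 ± 0.64), whose direction is opposite to a loss of the gene. Of 32 chemokines, 7 were higher in the same way, with Ccl7 (2.78 ± 0.38), Ccl2 (2.64 ± 0.40), Cxcl1 (3.95 ± 0.73) and Cxcl12 (0.96 ± 0.20) leading. Of 19 endothelial genes, 7 were higher, led by Sele (2.60 ± 0.40) and Selp (2.60 ± 0.41). Of 22 protease and matrix genes, 7 were higher, led by Adamts4 (2.60 ± 0.29) and Mmp19 (1.56 ± 0.18). Il1r1 (1.37 ± 0.20) and Pdgfra (1.48 ± 0.24) each passed within their own list. Camera gave these 4 lists adjusted p = 6.61e-09, 1.26e-08, 1.48e-15 and 2.42e-14, and with an estimated correlation the adjusted p was 0.202, 0.352, 0.352 and 0.352. Over all genes, edgeR's quasi-likelihood test called 0 of 15691. The smallest adjusted p was 0.069, for the hyaluronan synthase Has1 (log2 difference 3.69 ± 0.21), a gene named after its value was seen. At an unadjusted p under 0.05 there were 1145 genes (748 higher, 397 lower) where chance gives 785, and other splits of these libraries were not run. limma-voom called 0 and DESeq2 213 (163 higher, 50 lower). Il17c differed by -0.74 ± 0.65 (adjusted p = 0.866). Camera called 17 lists. Those not yet named were other cytokines (median 0.66), monocytes and macrophages (0.91), fibroblasts (1.04), neutrophils (0.74), interferon response (0.41), dendritic cells (0.25), antimicrobial response (0.55) and immediate early genes (0.73) upwards, and hair follicle (-2.19), melanocytes (-1.22), skeletal muscle (-0.72), T cells (-0.40) and cornified envelope (-0.30) downwards. All 17 were lost with an estimated correlation (adjusted p between 0.202 and 0.711). Without mouse 2465 the medians were -0.027 for skeletal muscle, where camera's direction turned, 0.17 for cornified envelope and -0.32 for immediate early genes, and without mouse 2296 camera's direction turned for cornified envelope (median -0.39). Without mouse 2392 the medians of chemokines and interferon response were -0.018 and -0.00864, and without mouse 2296 that of dendritic cells was -0.081.

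In uninvolved skin, the same comparison showed large differences in hair follicle genes, none of which passed a threshold in edgeR's quasi-likelihood test. DESeq2 called 1 of them, Krt32 (log2 difference -4.56, DESeq2 adjusted p = 0.0135). All 37 genes of the anagen list, which holds keratins and associated proteins of the growing hair, were lower in the libraries labelled IL-17C+KO, with a median of -6.39 log2 units, and 33 of them had an unadjusted p under 0.05 (camera adjusted p = 7.22e-26, adjusted p = 0.588 with an estimated correlation). The smallest p adjusted over the list alone was 0.0501, shared by Krtap4-16 (-6.40 ± 2.06), Krt72 (-7.99 ± 2.58), Krt32 (-4.55 ± 1.499) and Krt82 (-7.24 ± 2.42). Krtap4-16 belongs to a family of similar genes and is uncertain. The 10 melanocyte genes followed, with a median of -2.69. Uninvolved skin of mouse 2275 had little hair follicle signal as well (Krt72 at 0.637 CPM, against 64.0 and 271 CPM in mice 2296 and 2237, and 0.384 and 0.492 CPM in the libraries labelled IL-17C+KO). Cell cycle genes had a median of -0.97 and endothelial genes of 0.96. Il6 (3.25 ± 0.55) was the only IL-6 family gene past the threshold adjusted over the list alone. Fcer1a, the IgE receptor subunit of mast cells (-4.14 ± 0.91), and Slc4a1 of red blood cells (-3.70 ± 1.13) also passed in their lists. Xist (-0.93 ± 0.35) is the single tested member of the sex-linked list, so its quasi-likelihood p of 0.031 there is unadjusted. Il17c differed by -2.58 ± 1.11 (adjusted p = 0.849).

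Over all genes edgeR's quasi-likelihood test called 0 of 15568 in uninvolved skin, with 581 at an unadjusted p under 0.05 where chance gives 778. limma-voom called 0 and DESeq2 11, among them Il6, Fcer1a and the hair follicle gene Krt32. Without mouse 2275 the count was 241 (83 higher, 158 lower). Camera called 15 of 28 lists. Besides those named, skeletal muscle (median 1.11), Schwann cells (0.68), monocytes and macrophages (0.56), fibroblasts (0.49), dendritic cells (0.46), interferon response (0.38), IL-6 family (0.34) and proteases and matrix remodelling (0.30) were called upwards and B and plasma cells (-1.22) downwards, with adjusted p between 0.588 and 0.75 with an estimated correlation. The hair follicle, melanocyte, cell cycle and endothelium lists had adjusted p = 0.588, 0.594, 0.594 and 0.588 with an estimated correlation, and 0 lists were called that way. The antimicrobial (median -0.995) and keratinocyte activation (-0.84) lists were among those called downwards, and with the hair follicle score of each library as a covariate, added after the data were seen, their medians were 0.88 and 1.15, and that of interferon response -0.11. Without mouse 2465 camera's direction turned for keratinocyte activation (median -0.10) and the median of interferon response was -0.26, and without mouse 2392 that of proteases and matrix remodelling was -0.18. Xist was expressed in all 10 libraries (90.9 to 264 CPM), and its p adjusted over all genes was 0.849 in uninvolved skin. Of the Y chromosome genes, Ddx3y had at most 5 counts in a library and Kdm5d, Uty and Eif2s3y at most 1, as in female animals.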

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

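Of the tests in this part, all those of explanations (Il6, mouse 2237 and skeletal muscle) were chosen after the result was seen; the list tests of the interaction were fixed earlier.

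A difference between the 2 genotype labels drew attention to 14 gene lists, for which camera with a preset correlation called the interaction. The median difference of the lesional change, IL-17C+KO minus IL-17C+, was 2.21 for antimicrobial response, 1.63 for neutrophils, 1.29 for keratinocyte activation, 1.03 for proteases and matrix remodelling, 0.86 for cell cycle and 0.66 for B and plasma cells. It was 0.50 for chemokines, 0.49 for monocytes and macrophages, 0.46 for the IL-1 and IL-36 family, 0.45 for other cytokines, 0.44 for fibroblasts and collagen and 0.17 for the IL-6 family, and -2.54 for skeletal muscle and -0.65 for Schwann cells and nerve. Each call was lost with an estimated correlation, where the adjusted p lay between 0.317 and 0.907, and the number called was 23 without mouse 2392. The median turned to -0.47 for monocytes and macrophages without mouse 2392, and to -0.14 for fibroblasts, -0.24 for keratinocyte activation and -0.048 for the IL-1 and IL-36 family without mouse 2465.

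A signal outside the counts was seen in 61 genes, which had a count of 0 and an FPKM above 1 in all 10 libraries. They include the haemoglobin genes Hba-a1 (86.5 to 453 FPKM) and Hbb-b2 (81.0 to 603 FPKM) and the ribosomal gene Rps27rt (3667 to 9816 FPKM), so a count of 0 does not show absence for such genes.

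Il6 counts were higher in the libraries labelled IL-17C+KO, the gene named as knocked out. A wrong label of a single mouse is argued against, because the lowest IL-17C+KO library lay 4.39 times above the highest IL-17C+ library in lesional skin and 5.68 times in uninvolved skin. Counting noise is argued against by an exact binomial test of the 2 closest uninvolved libraries, which covers counting error only (two-sided exact p = 2e-09). A disrupted allele that is still transcribed, or an exchange of the 2 group names, may give the 9.59-fold ratio of mean CPM in uninvolved skin, and whole-gene counts cannot decide between them. Coverage per exon would be needed, and a biological difference between the mice other than the named knockout was not tested.

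In mouse 2237 the median lesional difference lay near 0 for the antimicrobial (0.02), keratinocyte activation (-0.01) and skeletal muscle (0.03) lists, but it was the highest of the 5 mice for the IL-6 family (0.76), endothelium (0.82) and the IL-17 axis (0.61). Its uninvolved biopsy had a median log2 CPM of 4.48 for the antimicrobial list (other uninvolved 1.05 to 3.68, lesional 4.40 to 6.60). For skeletal muscle it was 7.87 (other uninvolved 8.79 to 10.86, lesional 4.97 to 8.08). Keratinocyte activation (6.80) lay within the other uninvolved libraries (4.08 to 7.44). Neutrophil genes were low in both biopsies of mouse 2237 (-0.43 and 0.14, other lesional 2.25 to 4.94). An exchange of its 2 biopsies is argued against by the protease and matrix list, whose median difference in this mouse was 0.99 with 21 of 22 members higher in the lesional biopsy. A similar level of the transgene in both biopsies stays open: the log2 difference of Il17c in this mouse was -0.52, the lowest of the 5 mice. Mouse 2392 had a difference nearer 0 (0.30), and medians of 2.50 for the antimicrobial list and -2.56 for skeletal muscle. It carries the other label and had a lower Il17c level (1901 and 2347 CPM) than mouse 2237 (15180 and 10600 CPM), so it cannot decide the question.

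Of 24 skeletal muscle genes, 17 fell adjusted over the list alone in lesional skin of IL-17C+KO mice and 0 in IL-17C+ mice. The difference between the labels had an adjusted p = 0.317 with an estimated correlation. Single mice did not separate by label. The median lesional difference over the list was -3.046, -1.915 and 0.034 in IL-17C+ mice 2275, 2296 and 2237. In IL-17C+KO mice 2465 and 2392 it was -5.777 and -2.555, so the fall was larger in mouse 2275 than in mouse 2392. A smaller share of muscle in the lesional biopsies stays open: 22 of the 24 members had negative values in IL-17C+ mice and 24 of 24 in IL-17C+KO mice, but this is the pattern itself and cannot favour it. A fall confined to sarcomere transcripts is argued against by 6 muscle genes outside the sarcomere (Mb, Ckm, Eno3, Pvalb, Atp2a1 and Casq1). Their median log2 change was -4.09 in IL-17C+KO mice, each below -2.95. They are members of the same list, so they cannot show whether the amount of muscle was unchanged. Whether the depth of the biopsies differed is not given in the sources used here.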

How the results depend on the processing

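The alternatives added after the data were seen are limma-voom, limma on FPKM, the hair score covariate and the average over the 5 mice; the others were fixed before. Scaling by relative log expression left all 681 values of named genes, 168 list results and 12 counts on the same side of their thresholds or within 1.5 times. No named gene changed direction where a test called it. The cause was not tested for any change given here. Fewer mice give fewer degrees of freedom, but some counts rose when a mouse was left out. Where mouse 2392 or 2465 is left out, the lone IL-17C+KO mouse is assumed to vary like the other groups. Depth limits genes near 3 counts per library.

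DESeq2 called 247 genes in IL-17C+ mice, 1157 in IL-17C+KO mice, 6 for the interaction, 213 in lesional skin, 11 in uninvolved skin and 2036 for the average over the 5 mice, against 0, 2, 0, 0, 0 and 8 in edgeR. With an estimated correlation 0 lists were called in each of the 6 comparisons, against 18, 20, 14, 17, 15 and 19. With no filter on low counts, edgeR called 5 genes in IL-17C+KO mice, 1 in lesional skin and 15 for the average. With no replicate block it called 0 in IL-17C+KO mice and 966 for the average, and the block changed no other count by over 1.5 times. It called 0 in the libraries of the IL-17C+KO genotype only. For the average, a mean of at least 5 CPM left 3 genes, limma-voom called 4, limma on log2 FPKM 15 and the hair score covariate 0.

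Leaving out 1 mouse gave 0 to 11 genes in IL-17C+KO mice (11 without mouse 2237, 0 without 2296, 2392 or 2465), 0 to 241 in uninvolved skin (241 without mouse 2275), 0 to 1249 for the average (1249 without mouse 2237) and 14 to 23 lists for the interaction (23 without mouse 2392).

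For lists called by camera whose camera direction changed, the median is given as the range over the mice left out; lists that were not called are not given. In IL-17C+ mice this was hair follicle (-0.47 without 2275, to 4.01). In IL-17C+KO mice these were hair follicle (-1.23 without 2465, to 6.46), sebaceous gland (-1.30 to 0.088 without 2465), monocytes (-0.054 without 2392, to 1.80), adipocytes (-3.13 to 0.49 without 2465) and immediate early genes (-0.064 without 2465, to 1.67). For the interaction they were keratinocyte activation (-0.24 without 2465, to 2.99), monocytes (-0.47 without 2392, to 1.23) and fibroblasts (-0.14 without 2465, to 1.08). In lesional skin they were cornified envelope (-1.03 to 0.17 without 2465, and -0.39 without 2296), skeletal muscle (-2.47 to -0.027 without 2465) and immediate early genes (-0.32 without 2465, to 1.32). In uninvolved skin they were keratinocyte activation (-2.56 to -0.10 without 2465) and interferon response (-0.26 without 2465, to 0.82). With the hair score covariate, uninvolved skin gave 0.88 for antimicrobial response, 1.15 for keratinocyte activation and -0.11 for interferon response. The sign of the median alone turned for the IL-1 family in the interaction (-0.048 without 2465), for chemokines (-0.018 without 2392), interferon response (-0.00864 without 2392) and dendritic cells (-0.081 without 2296) in lesional skin, and for proteases in uninvolved skin (-0.18 without 2392). With the covariate it turned for the IL-1 family in IL-17C+ mice (-0.0051) and antimicrobial response in lesional skin (-0.094).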

Other observations

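In this part, the average over the 5 mice and the test of genes near Il6 were chosen after the data were seen, and the splits of libraries were planned.

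Averaged over both genotypes, lesional skin differed from uninvolved skin at 8 genes past the threshold in edgeR's quasi-likelihood test, 7 higher and 1 lower, each in the same direction in 5 of 5 mice. Fibronectin (Fn1), a matrix glycoprotein, rose by 1.73 ± 0.16 log2 units (SE, 5 mice; adjusted p = 0.026), with 1.45 to 1.91 in single mice. Osm rose by 4.66 ± 0.36 (adjusted p = 0.026; 2.40 to 4.99 in single mice), Cxcl3 by 5.96 ± 0.54 (0.026; 2.81 to 7.29) and the epidermal protease Klk14 by 3.67 ± 0.36 (0.0322; 2.42 to 4.43). Mrgpra2a (4.11 ± 0.39; 0.81 to 3.96) and Gm53 (-3.23 ± 0.33; -3.50 to -2.31) also passed. Brinp3 and Speer4d passed with at most 0.0493 CPM in any uninvolved library, so their fitted values of 7.36 ± 0.62 and 6.70 ± 0.57 depend on the prior count. In single mice Brinp3 ran from 0.56 (mouse 2392, 0.0377 CPM in lesional skin) to 6.36, and Speer4d from 1.28 to 5.74. Speer4d and Mrgpra2a belong to families of similar genes and are uncertain. The count was 1249 without mouse 2237 and 0 without any other single mouse. It was 0 with the hair score covariate, 3 at a mean of at least 5 CPM, 966 with no replicate block and 2036 in DESeq2.

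Gene lists gave a similar picture in that average. Adjusted over the list alone, 19 of 22 protease and matrix genes, 16 of 20 fibroblast genes, 11 of 13 neutrophil genes, 13 of 19 antimicrobial genes and 16 of 40 cell cycle genes rose, and 16 of 24 skeletal muscle genes fell. Of 45 cornified envelope genes, members of families of similar sequence, 15 rose and 18 fell in the same way, and camera did not call the list (adjusted p = 0.744). Camera called 19 of 28 lists. With an estimated correlation it called 0, where these 6 lists had adjusted p = 0.234, 0.234, 0.234, 0.31, 0.41 and 0.31. The self-contained fry test called 5 lists: IL-6 family, proteases and matrix remodelling, mast cells and eosinophils, and fibroblasts (adjusted p = 0.0393 each) and neutrophils (0.0499).

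The 6 IL-17C+ libraries were also split into 3 and 3 in every way, without the mouse block. The real split gave 1465 genes at an unadjusted p under 0.05 and the highest other split 1681, and 3 of the 10 splits gave as many genes as the real one, itself included. In DESeq2 the real split gave 409 genes past the threshold and the highest other split 153. With 10 splits the share cannot fall under 0.05. With the block, the 4 splits that part every pair gave 1031 (real), 1347, 1396 and 70 genes in edgeR, and 247 (real), 220, 17 and 0 past the threshold in DESeq2.

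Abhd1 (GRCm38 chromosome 5, 30950066 to 30955091), 0.93 Mb from Il6, had 0 to 3 counts in the 6 IL-17C+ libraries and 20 to 62 in the 4 libraries labelled IL-17C+KO. A chromosome segment carried from another strain with the knockout could give such a difference. Of 184 tested genes within 10 Mb of Il6, 7 separated the 2 labels without overlap, against 449 of 15304 other genes (odds ratio 1.31, 95% interval 0.515 to 2.78; one-sided Fisher's exact p = 0.299), so the hypothesis stays open. Among all 16083 genes 472 separated the labels, where chance gives 0.952% for 4 libraries against 6, and the 2 libraries of a mouse are not independent.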
